A study of Mus musculus with 24 samples.

How the data were processed

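Gene expression was measured in 24 mouse samples on 24 Affymetrix whole-genome expression arrays. Per the labels, 5 mammary adenocarcinomas of C57BL6/J Apc+/1572T mice, which carry a truncating allele of the Wnt pathway regulator Apc, and 3 pools of mammary glands of Apc+/+ mice were dissociated and sorted. Lin- cells had been depleted of lineage-marked cells, Lin-CD29+CD24+ cells are the more differentiated gate, and Lin-CD29hiCD24+ cells are the gate used for stem cells. Each of the 3 populations was taken as 10000 cells, RNA was isolated with a micro column kit, and it was amplified and biotin-labelled in a two-cycle protocol. The tumours carry the letters A to E and the pools F to H in the sample titles; 2 titles of the third pool carry no letter and were taken as H by elimination. The 3 populations of a letter are pairs by these titles, and this was checked with the group means removed. Arrays of the same tumour correlated across genes with a median r of 0.578 over 15 pairs, against -0.167 over 60 pairs of different tumours. For pools the medians were 0.142 over 9 pairs and -0.071 over 18 pairs. Between the CD29+CD24+ and CD29hiCD24+ arrays of a pool r was -0.038 (F), -0.016 (G) and 0.142 (H), against up to 0.161 between pools, so this does not bear out their pairing in F and G.

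The values are those deposited by the authors, a log2 signal per probe set, background-corrected, normalised and summarised before deposit. Processing notes in the labels name RMA, GCRMA and Partek, and the version, role and order of each are not given in the sources used here. The log2 scale was read from the values themselves, which ran from 0.489 to 16.06. Between 37.2% and 41.6% of the values of an array lay in a narrow band at or under 2.83, the 40th percentile of all values, called the low band below. Array medians ran from 3.26 to 3.41. Differences that start from the low band are compressed, since background removal leaves little signal there. The number of arrays, not a depth, limits the precision.

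Of 45101 probe sets, 34958 had 1 gene name, 932 had several, 9160 had none and 64 were controls. Gene results rest on the probe sets with 1 gene name, and 34754 of these also matched a gene identifier of the reference annotation, with 0 names changed. Probe sets over the 40th percentile of all values in at least 3 arrays were kept, which left 24278 probe sets. The kept probe set with the highest mean over the 24 arrays stood for its gene, so 13485 genes were tested of 18193 before the filter. Gene positions were not used here. List members with no kept probe set of their own name were not analysed here.

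limma version 3.58.1 in R version 4.3.3 fitted 1 mean to each of the 6 groups (3 populations in tumour and normal) over the 24 arrays, with lmFit, contrasts.fit and eBayes with a trend of variance on mean signal. There were 8 contrasts. They are tumour against normal in each of the 3 populations, CD29hiCD24+ against CD29+CD24+ and against Lin- within normal glands and within tumours, and the difference between tumour and normal in the first of these gate contrasts. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. Values after ± are standard errors of a log2 difference, or standard deviations of a group mean where SD is written. A log2 difference of 1 is a 2-fold difference. Genes called with the same sign in both CD29hiCD24+ against CD29+CD24+ contrasts, which share no array, were counted and compared with the count for independent lists by Fisher's exact test, two-sided.

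The tests, the alternatives, the rule for naming genes and 24 gene lists were chosen before the data were examined, apart from 3 alternatives named below. The lists are basal and myoepithelial, luminal epithelial, milk and secretory, mammary stem cell associated, Wnt/beta-catenin targets, secreted Wnt antagonists, Wnt ligands, Notch pathway, mesenchymal transition, epithelial junction, fibroblast and matrix, endothelial, pericyte, leukocyte, erythroid, adipocyte, skeletal muscle, Schwann and glial, proliferation, squamous keratinisation, hair follicle differentiation, hypoxia and glycolysis, dissociation and immediate early response, and interferon response. The erythroid list had fewer than 3 measured members and was not tested, which left 23 lists and 184 tests of a list in a contrast. Some genes stand in more than 1 list, as Wif1 and Notum do in both the Wnt target and the Wnt antagonist lists. Each list was tested with camera at a preset correlation of 0.01 between genes, with adjustment over the lists of a contrast. Camera with an estimated correlation and fry were run beside it. Member counts are of called genes, over all genes tested and adjusted over the list alone.

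Genes were named by rule. In the 4 main contrasts these were the 10 highest and 10 lowest log2 differences among called genes whose groups did not overlap. In the other 4 contrasts they were the 5 highest and 5 lowest by the same rule. Genes given below as highest or lowest are so by this rule, and called genes with overlapping groups can differ more. Up to 4 called members of each list were added, or 2 with the smallest p where no member was called, and always Apc and the sort markers Itgb1 (CD29) and Cd24a (CD24). Predicted genes and clone names were skipped.

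Alternatives were a replicate block for the 3 populations of 1 tumour or pool (fixed for contrasts within tumours or normals and for their difference, random for tumour against normal), the same without pool H, and a fit of only the groups compared. Others were no filter, a filter at the 60th percentile, the mean of or all of a gene's probe sets, quantile normalisation, median centring, eBayes without trend or with robust estimation, array weights, a spread of their own for tumour and normal, and a 2-fold threshold. Further ones were the actin 3' minus 5' signal as covariate, a block by the number in the description label (19 to 24, 56 to 64 and 82 to 95), which the labels do not call a batch, and leaving out each tumour or pool with all its arrays. Only tumour E lies in the number range of the pools, so with this block the level of tumour against normal rests on tumour E alone. Chosen after seeing the data were leaving out the CD29hiCD24+ array of pool F, tumour E alone against the 3 pools, and the mean of the leukocyte list as covariate. The procedure was tested on simulated data with the same groups and spread per gene, with 100 genes changed by 1 log2 unit and 100 by 2 in each contrast. The simulated arrays were independent, with no shared tumour or pool effect. Fewer genes were changed than were called in any real contrast, so the shares found do not give the power in the real data.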

Results

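The data are log2 signals of 13485 genes in 24 arrays. There were 5 arrays for each of the tumour Lin-, CD29+CD24+ and CD29hiCD24+ populations, from tumours A to E, and 3 arrays for each of the same normal populations, from gland pools F to H. The first principal component held 47.5% of the variance and parted tumour arrays from normal ones, and the second, with 19.9%, parted normal CD29hiCD24+ arrays from the other normal arrays. Correlations within a group ran from 0.950 to 0.991. The 3' minus 5' signal of actin, a sign of RNA shortening, was 2.53 ± 0.35 (SD, n = 3) in normal CD29hiCD24+ and 1.61 ± 0.21 (SD, n = 3) in normal CD29+CD24+ arrays, and 2.03 ± 0.30 and 2.06 ± 0.36 (SD, n = 5 each) in the same tumour populations.

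**Figure D1:**
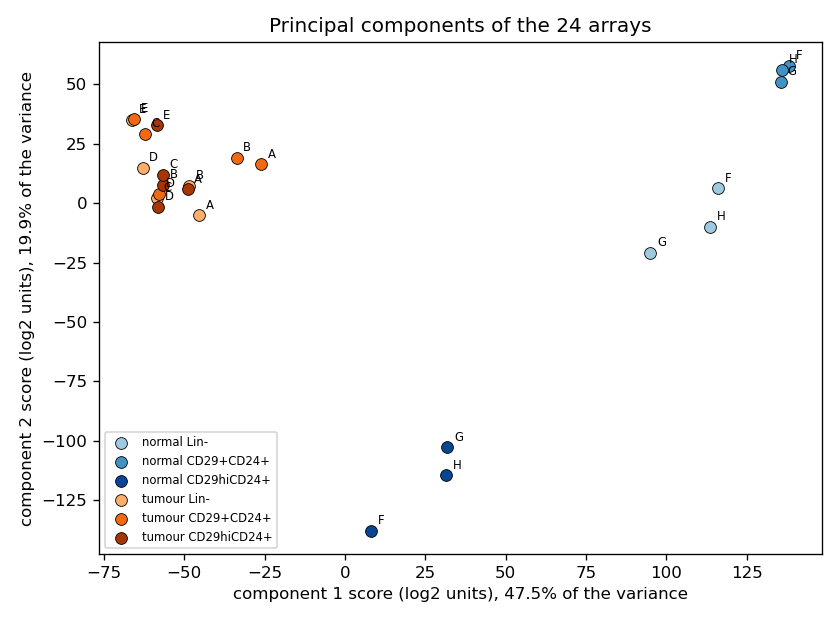
Scores of the 24 arrays on the first 2 principal components of the log2 signals (axes in log2 units, with the share of variance), coloured by group and lettered by tumour or pool. Tumour arrays of all 3 populations lie together, and normal CD29hiCD24+ arrays lie apart from the other normal arrays on component 2.

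The first aim stated for the series is to compare normal CD29hiCD24+ cells with tumour CD29hiCD24+ cells. Among the 10 genes most raised in the 5 tumours over the 3 pools were Krt79, higher by 10.49 ± 0.45, Krt6b by 8.94 ± 0.50 and Krtdap, a keratinocyte differentiation gene, by 8.86 ± 0.44. S100a8 (9.09 ± 0.80) and S100a9 (9.01 ± 0.57), the subunits of calprotectin, were among them too, as were Nppb (8.91 ± 0.92), the mitochondrial creatine kinase Ckmt1 (8.51 ± 0.31), Dynap (8.19 ± 0.65), the protease Klk8 (8.17 ± 0.77) and Cwh43 (8.10 ± 0.35). Lowest in tumours were Glycam1 (-8.25 ± 2.19), the cytokine Il17b (-7.96 ± 0.59), the smooth muscle genes Cnn1 (-7.19 ± 0.77) and Myh11 (-6.99 ± 0.85), Kcnq5 (-7.18 ± 0.52), Fam107a (-7.10 ± 0.62), Pgm5 (-7.06 ± 0.39), the growth factor Mdk (-6.89 ± 0.56), and the endothelial genes Vwf (-7.00 ± 1.20) and Selp (-6.88 ± 1.06). The adjusted p of these 20 genes ran from 2.96e-14 (Ckmt1) to 0.00502 (Glycam1). That every tumour array lay on the same side of every normal array for them follows from the naming rule. Normal means of Krt79, S100a9, Krt6b, Nppb, Dynap and Cwh43 lay in the low band, as did the tumour means of Il17b, Kcnq5 and Pgm5.

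Proliferation genes were higher in tumour CD29hiCD24+ cells, where 20 of 21 measured members rose and 0 fell (20 and 0 adjusted over the list alone), with Mki67 at 5.33 ± 0.52 and Cdk1 at 4.98 ± 0.69 and a list median of 4.02. The proliferation list gave a camera adjusted p of 1.27e-14, and adjusted p = 0.202 with an estimated correlation. Among squamous keratinisation genes 10 of 17 measured members rose and 0 fell (10 and 0 adjusted over the list alone), with Sprr2d at 7.02 ± 0.89 and Krt6a at 5.08 ± 0.40. The keratinisation list gave a camera adjusted p of 6.94e-07, and adjusted p = 0.216 with an estimated correlation. Hypoxia and glycolysis genes were higher too, as 12 of 18 measured members rose and 0 fell (14 and 0 adjusted over the list alone), with Car9, a carbonic anhydrase induced by hypoxia, at 4.37 ± 0.59 and Hk2, a hexokinase, at 2.54 ± 0.18. The hypoxia list gave a camera adjusted p of 6.94e-07, and adjusted p = 0.202 with an estimated correlation. In the epithelial junction list 8 of 20 measured members rose and 1 fell (8 and 1 adjusted over the list alone), with Ovol1 at 5.64 ± 0.48 and Rab25 at 2.53 ± 0.43. The junction list gave a camera adjusted p of 0.0110, and adjusted p = 0.623 with an estimated correlation. Endothelial markers were lower, since 0 of 13 measured members rose and 12 fell (0 and 13 adjusted over the list alone), with Plvap at -5.74 ± 0.85 and Cldn5 at -5.45 ± 0.69. The endothelial list gave a camera adjusted p of 8.55e-06, and adjusted p = 0.572 with an estimated correlation. The normal CD29hiCD24+ array of pool F had an endothelial mean of 8.88 against 6.03 and 6.84 in pools G and H, a leukocyte mean of 8.56 against 3.44 and 3.37, and a luminal mean of 6.76 against 8.96 and 8.95. Without that array, 10 of the 13 endothelial markers were still lower, and the epithelial junction call was lost (camera adjusted p = 0.0959).

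Basal and myoepithelial genes went both ways, as 3 of 20 measured members rose and 10 fell (3 and 10 adjusted over the list alone), and the contractile genes Actg2 (-6.84 ± 0.68) and Oxtr (-6.70 ± 0.72), the oxytocin receptor, fell with Cnn1 and Myh11. The basal list gave a camera adjusted p of 0.0624, and adjusted p = 0.785 with an estimated correlation. The basal list was called lower with the replicate block (camera adjusted p = 0.00858), after quantile normalisation (0.0236) and without the array of pool F (0.0281). It was so as well with no low-value filter (camera adjusted p = 0.0147) and with the description-number block (0.0291). Pericyte markers had 1 higher and 3 lower of 6 (1 and 3 adjusted over the list alone), with Mcam at -4.13 ± 0.75 and Cspg4 at 3.81 ± 0.74, and were not called (camera adjusted p = 0.614), and the list mean was 4.39 to 5.58 in tumour and 5.88 to 6.51 in normal arrays. Fibroblast and matrix genes had 1 higher and 5 lower of 20 (1 and 5 adjusted over the list alone), with Postn at -4.63 ± 0.85 and Fbln1 at 4.36 ± 0.52, and were not called (camera adjusted p = 0.315), with list means of 5.14 to 6.12 and 6.19 to 7.14. Wnt/beta-catenin targets were also split, with 8 higher and 6 lower of 19 (9 and 6 adjusted over the list alone), and the feedback inhibitors Notum (4.45 ± 0.45), Axin2 (3.35 ± 0.35) and Nkd2 (3.29 ± 0.59) were higher. The Wnt target list gave a camera adjusted p of 0.149, and adjusted p = 0.785 with an estimated correlation. Mammary stem cell associated genes had 3 higher and 6 lower of 16 (4 and 7 adjusted over the list alone), with Vcam1 at -4.84 ± 1.07 and Tspan8 at -4.15 ± 0.59. The stem cell list gave a camera adjusted p of 0.785, and adjusted p = 0.907 with an estimated correlation. Luminal genes had 3 higher and 11 lower of 22 (4 and 13 adjusted over the list alone), with the transcription factor Ehf at 6.35 ± 0.58 and the progesterone receptor Pgr at -4.00 ± 0.58. The luminal list gave a camera adjusted p of 0.228, and adjusted p = 0.868 with an estimated correlation. It was called lower without the array of pool F (camera adjusted p = 0.0138) and with the description-number block (0.0132).

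Altogether 5199 of 13485 genes differed (38.6%), 2105 higher and 3094 lower in tumours, and 3418 of them by at least 2-fold. After quantile normalisation 2882 were higher and 2483 lower. The groups did not overlap for 4986 genes (37.0%), where chance gives 3.57%. Per the labels, only tumour E shares its range of description numbers (82 to 95) with the pools. With a block for these ranges 6190 genes differed, 4680 of the 5199 among them with the same sign. In that fit the level of tumour against normal rests on tumour E alone. The 5199 genes were called with tumour E among the arrays, so this share is no separate check. In simulated data the test found 52 of 100 genes changed by 1 log2 unit and 84 of 100 changed by 2.

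The second aim is to compare stem cell gates with their differentiated counterparts. In normal glands (n = 3 pools), CD29hiCD24+ cells differed from CD29+CD24+ cells as basal from luminal cells do. Among the 10 genes most raised were basal keratins and contractile genes, with Krt17 at 10.73 ± 0.59, Krt14 at 10.38 ± 0.46, the myosin light chain Myl9 at 11.11 ± 1.07, Tagln at 10.15 ± 1.27 and the hemidesmosome collagen Col17a1 at 10.36 ± 0.49. The other highest genes were the growth factor binding protein Igfbp3 (11.08 ± 0.67), Tenm2 (10.53 ± 0.66), the matrix genes Sparc (10.44 ± 0.48) and Postn (10.07 ± 0.95), and the sodium channel gene Scn7a (10.05 ± 1.08). The lowest were Olfm4 (-6.60 ± 1.66), Tesc (-6.06 ± 1.22), the uroplakin Upk3a (-5.90 ± 1.46), Dmbt1 (-5.89 ± 1.98), Ccdc162 (-5.80 ± 0.51), the EGF receptor ligand Btc (-5.80 ± 0.56), the fibrinogen chain Fgb (-5.77 ± 1.30), Aoc1 (-5.67 ± 0.96), Itih2 (-5.63 ± 0.85) and Rasgrf1 (-5.62 ± 0.93). Means in CD29+CD24+ arrays lay in the low band for Myl9, Krt17, Tenm2, Sparc, Col17a1 and Scn7a. The adjusted p of these 20 genes ran from 3.16e-13 (Krt14) to 0.0183 (Dmbt1). Dmbt1 lost its call without pool F (adjusted p = 0.277), with the actin covariate (0.174) and with only these groups fitted (0.0535), and Olfm4 and Upk3a lost theirs with the actin covariate (adjusted p = 0.0531 and 0.0599).

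In the basal and myoepithelial list 20 of 20 measured members rose and 0 fell (20 and 0 adjusted over the list alone), with a median of 8.93. The basal list gave a camera adjusted p of 1.10e-18, and adjusted p = 0.0343 with an estimated correlation. Luminal genes were lower, as 0 of 22 measured members rose and 16 fell (0 and 16 adjusted over the list alone), with the claudin gene Cldn4 at -5.34 ± 1.08 and Cited1 at -5.04 ± 1.07. The luminal list gave a camera adjusted p of 0.000166, and adjusted p = 0.437 with an estimated correlation. For mammary stem cell associated genes 11 of 16 measured members rose and 0 fell (12 and 0 adjusted over the list alone), with the transcription factors Snai2 at 9.49 ± 0.44 and Id4 at 9.47 ± 0.56. The stem cell list gave a camera adjusted p of 3.09e-07, and adjusted p = 0.0343 with an estimated correlation. Wnt/beta-catenin targets were higher, where 15 of 19 measured members rose and 1 fell (15 and 1 adjusted over the list alone), with the R-spondin receptor Lgr5 at 7.77 ± 0.61 and Ccnd2 at 8.41 ± 0.50. The Wnt target list gave a camera adjusted p of 5.04e-08, and adjusted p = 0.115 with an estimated correlation. Of secreted Wnt antagonists 5 of 10 measured members rose and 0 fell (5 and 0 adjusted over the list alone), with Wif1 at 8.15 ± 0.48 and Dkk3 at 7.14 ± 0.51. The Wnt antagonist list gave a camera adjusted p of 0.00310, and adjusted p = 0.0343 with an estimated correlation. In the mesenchymal transition list 10 of 18 measured members rose and 0 fell (10 and 0 adjusted over the list alone), with Mmp2 at 9.62 ± 0.52 and Vim at 8.44 ± 0.68. The mesenchymal list gave a camera adjusted p of 0.000247, and adjusted p = 0.115 with an estimated correlation. Epithelial junction genes were lower, since 0 of 20 measured members rose and 14 fell (0 and 14 adjusted over the list alone), with Cgn at -4.75 ± 0.66 and Prss8 at -4.40 ± 0.45. The junction list gave a camera adjusted p of 2.78e-05, and adjusted p = 0.115 with an estimated correlation.

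Markers of other cell types moved with this gate. Of endothelial markers 10 of 13 measured members rose and 0 fell (10 and 0 adjusted over the list alone), with Esam at 7.11 ± 0.84 and Plvap at 6.70 ± 0.95. The endothelial list gave a camera adjusted p of 0.000256, and adjusted p = 0.437 with an estimated correlation. Of fibroblast and matrix genes 11 of 20 measured members rose and 0 fell (11 and 0 adjusted over the list alone), with Serpinf1 at 5.57 ± 0.55 and Col6a1 at 6.39 ± 1.08. The fibroblast list gave a camera adjusted p of 0.00121, and adjusted p = 0.616 with an estimated correlation. Pericyte markers had 3 higher and 1 lower of 6 (3 and 1 adjusted over the list alone), with Mcam at 5.81 ± 0.84 and Notch3 at -3.02 ± 0.41, and were not called (camera adjusted p = 0.400), and the list mean was 5.88 to 6.51 in CD29hiCD24+ and 3.77 to 3.98 in CD29+CD24+ arrays. Adipocyte genes had 3 higher and 2 lower of 7 (3 and 2 adjusted over the list alone), with Fabp4 at 8.27 ± 1.38 and Lipe at -2.37 ± 0.27, and were not called (camera adjusted p = 0.664), with list means of 5.86 to 6.57 and 4.31 to 4.40. The leukocyte list had a median of 2.22, with 2 higher and 0 lower of 14 (1 and 0 adjusted over the list alone), and was not called (camera adjusted p = 0.0769), and it was high in the array of pool F alone, as given above. In all 6281 genes differed (46.6%), 2871 higher and 3410 lower in CD29hiCD24+ cells, and 5460 did so without that array, 5346 of them among the 6281 with the same sign. With the actin 3' minus 5' signal as covariate, which moves with this gate, 4914 genes differed, and higher ones were the larger part (2520 and 2394). The Gapdh 3' minus 5' signal was not higher in this gate, as given above. Groups did not overlap for 58.2% of genes, where chance gives 10% for 3 arrays against 3. Of 100 simulated genes changed by 1 log2 unit 41 were found, and of 100 changed by 2, 80 were found.

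In tumours (n = 5), the same gates differed far less. Highest in CD29hiCD24+ over CD29+CD24+ cells were Adam12 (4.13 ± 0.54), a metalloprotease gene, Ndufa4l2 (4.09 ± 0.64) and Car9 (4.04 ± 0.51), both induced by hypoxia, the smooth muscle actin Acta2 (3.80 ± 0.72), Myl9 (3.64 ± 0.83), the MHC class II gene H2-Ab1 (3.24 ± 0.68), Scn7a (3.21 ± 0.84), Vwa1 (3.19 ± 0.59), the collagen gene Col12a1 (3.14 ± 0.67) and Prelid2 (3.10 ± 0.24). Lowest were genes of cornifying keratinocytes, with the desmosomal cadherins Dsc1 (-4.62 ± 0.87), Dsg1a (-3.66 ± 0.47) and Dsg1b (-3.34 ± 0.29), Casp14 (-3.49 ± 0.73), a caspase of epidermal differentiation, Scel (-3.35 ± 0.45) and the lipid transporter Abca12 (-3.03 ± 0.44). The glucose transporter Slc5a1 (-4.38 ± 0.68), Dapl1 (-3.62 ± 0.49), Slc6a14 (-3.17 ± 0.48) and Tmprss4 (-3.02 ± 0.51) were the other 4 of the 10 lowest among called genes whose groups did not overlap. Their adjusted p ran from 5.04e-07 (Prelid2) to 0.0346 (Scn7a), and for all 20 every CD29hiCD24+ array lay on the same side of every CD29+CD24+ array. Without 1 tumour or pool, Myl9 lost its call (B, adjusted p = 0.0603), as did Col12a1 (B, 0.0667), H2-Ab1 (A or E, up to 0.0576) and Scn7a (any but E, up to 0.146). With only these groups fitted, Dsc1, Casp14 and Scn7a lost theirs (adjusted p = 0.0541, 0.0754 and 0.107), and Scn7a did with the leukocyte covariate (0.0605).

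Hypoxia and glycolysis genes were higher in tumour CD29hiCD24+ cells, where 9 of 18 measured members rose and 0 fell (16 and 1 adjusted over the list alone), with Bnip3 at 2.45 ± 0.36 and a list median of 0.73. The hypoxia list gave a camera adjusted p of 7.54e-12, and adjusted p = 0.0214 with an estimated correlation. The list mean was higher in the CD29hiCD24+ array of each of the 5 tumours, by 0.71 to 1.28. The mean of the proliferation list was higher in all 5 as well, by 0.09 to 1.53, and 3 of 21 measured members rose and 0 fell (16 and 0 adjusted over the list alone), with the cell cycle factor Foxm1 at 1.46 ± 0.25 and Tyms at 0.67 ± 0.12, calls that were lost with only these groups fitted (adjusted p = 0.0800 and 0.0925). The proliferation list gave a camera adjusted p of 3.23e-11, and adjusted p = 0.212 with an estimated correlation. Squamous keratinisation genes were lower, as 0 of 17 measured members rose and 5 fell (1 and 7 adjusted over the list alone), with Sprr1a at -2.90 ± 0.47. The keratinisation list gave a camera adjusted p of 1.14e-05, and adjusted p = 0.237 with an estimated correlation. Among luminal genes 0 of 22 measured members rose and 4 fell (0 and 8 adjusted over the list alone), with Elf5 at -2.88 ± 0.73 and Aldh1a3 at -2.24 ± 0.57. Both genes lost their calls without any 1 of the 5 tumours (adjusted p up to 0.115 and 0.118) and with the leukocyte covariate (0.0619 and 0.0566). The luminal list gave a camera adjusted p of 1.12e-06, and adjusted p = 0.312 with an estimated correlation. The luminal mean was lower in the CD29hiCD24+ array of all 5 tumours, with differences from -2.72 to -0.21. Of basal and myoepithelial genes 2 of 20 measured members rose and 0 fell (8 and 0 adjusted over the list alone), namely Acta2 and Cnn1 (2.73 ± 0.67), and Cnn1 lost its call without A, B, C or D (adjusted p up to 0.107) and with only these groups fitted (0.0835). The basal list gave a camera adjusted p of 3.44e-06, and adjusted p = 0.319 with an estimated correlation. Its mean was higher in the CD29hiCD24+ array of all 5 tumours, by 1.23 to 1.60 in A to D and by only 0.17 in E.

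Epithelial junction genes were lower in this contrast, with 0 higher and 5 lower of 20 (0 and 11 adjusted over the list alone), Marveld2 at -1.81 ± 0.31 among them. The junction list gave a camera adjusted p of 1.12e-06, and adjusted p = 0.114 with an estimated correlation. Wnt ligands had 1 higher and 0 lower of 11 (2 and 0 adjusted over the list alone), with Wnt9a at 2.04 ± 0.23. The Wnt ligand list gave a camera adjusted p of 0.00540, and adjusted p = 0.114 with an estimated correlation. The mean of the leukocyte list was higher in the CD29hiCD24+ array of all 5 tumours, by 0.57 to 1.91, and its members had 1 higher and 0 lower of 14 (1 and 0 adjusted over the list alone). The leukocyte list gave a camera adjusted p of 0.0120, and adjusted p = 0.785 with an estimated correlation. The mean of the interferon response list was higher in all 5 as well, by 0.21 to 1.41, and its members had 0 higher and 0 lower of 16 (0 and 0 adjusted over the list alone). The interferon list gave a camera adjusted p of 0.0120, and adjusted p = 0.785 with an estimated correlation. After quantile normalisation the leukocyte call was lost (camera adjusted p = 0.0714). The mammary stem cell list had 0 higher and 0 lower of 16 (0 and 0 adjusted over the list alone) and the Wnt/beta-catenin targets 0 higher and 1 lower of 19 (0 and 1 adjusted over the list alone), and neither list was called (camera adjusted p = 0.704 and 0.113). Notum was lower (-2.10 ± 0.39), and not called with only these groups fitted (adjusted p = 0.0502). With the replicate block the Wnt target list was called lower (camera adjusted p = 0.0242) and the mesenchymal transition list higher (camera adjusted p = 0.039).

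In all 565 genes differed between the tumour gates (4.19%), 304 higher and 261 lower in CD29hiCD24+ cells, or 491 and 215 after quantile normalisation and 308 and 311 with the 60th percentile filter, and 2633 passed an unadjusted p of 0.05. With the replicate block 2080 genes differed, 1033 higher and 1047 lower, all 565 among them. The count moved to 149 when only these 2 groups were fitted, to 1028 with array weights, to 1263 with the description-number block, and to 297, 207, 340, 245 and 371 without tumours A, B, C and E and pool H. Groups did not overlap for 681 genes (5.05%), where chance gives 0.794%, and the simulated data gave 53 and 91 of 100 genes at 1 and 2 log2 units.

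The difference between the tumour and the normal gate contrast was tested directly. It was most negative for genes that part the gates in normal glands and did not pass the test in tumours, such as Igfbp3 (-11.12 ± 0.85), Krt17 (-10.69 ± 0.74), Krt14 (-10.35 ± 0.58), Mmp2 (-9.97 ± 0.65), Col5a2 (-9.92 ± 0.71), Fhod3 (-9.85 ± 0.91), Id4 (-9.75 ± 0.71), Snai2 (-9.75 ± 0.56) and Sparc (-9.73 ± 0.61). Glycam1 (-10.25 ± 3.10) was also among the 10 lowest and lost its call without pool F (adjusted p = 0.0530). The most positive differences were those of Aoc1 (6.68 ± 1.22), Tesc (6.27 ± 1.54), Qsox1 (6.18 ± 0.94), Akr1c13 (6.16 ± 0.83), Steap1 (5.92 ± 0.64), the mitotic kinesin Kif2c (5.76 ± 0.61), Lgals3bp (5.59 ± 2.005), Ttc39a (5.43 ± 0.79), Ccdc162 (5.43 ± 0.64) and Syn2 (5.37 ± 0.84). Lgals3bp lost its call without C, F, G or H (adjusted p up to 0.122) and with the actin covariate (3.35, adjusted p = 0.254). Krt14 shows the pattern in signal, at 14.35 in normal CD29hiCD24+, 3.97 in normal CD29+CD24+, and 14.67 and 14.64 in the same tumour gates.

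Basal and myoepithelial genes had 0 higher and 20 lower of 20 (0 and 20 adjusted over the list alone) in this difference, with a median of -6.90. The basal list gave a camera adjusted p of 5.05e-16, and adjusted p = 0.0584 with an estimated correlation. Wnt/beta-catenin targets had 0 higher and 17 lower of 19 (1 and 18 adjusted over the list alone), with Wif1 at -8.31 ± 0.60, Lgr5 at -8.36 ± 0.77 and Bambi at -6.88 ± 0.62. The Wnt target list gave a camera adjusted p of 3.50e-09, and adjusted p = 0.102 with an estimated correlation. Mammary stem cell associated genes had 0 higher and 10 lower of 16 (0 and 11 adjusted over the list alone). The stem cell list gave a camera adjusted p of 1.62e-06, and adjusted p = 0.0584 with an estimated correlation. Secreted Wnt antagonists had 0 higher and 6 lower of 10 (0 and 6 adjusted over the list alone), with Sfrp1 at -5.63 ± 0.61. The Wnt antagonist list gave a camera adjusted p of 0.00231, and adjusted p = 0.0584 with an estimated correlation. Epithelial junction genes went the other way with 13 higher and 0 lower of 20 (13 and 0 adjusted over the list alone). The junction list gave a camera adjusted p of 0.00477, and adjusted p = 0.410 with an estimated correlation. Mesenchymal transition genes had 1 higher and 9 lower of 18 (2 and 10 adjusted over the list alone). The mesenchymal list gave a camera adjusted p of 0.00333, and adjusted p = 0.257 with an estimated correlation. Endothelial markers had 0 higher and 9 lower of 13 (0 and 9 adjusted over the list alone). The endothelial list gave a camera adjusted p of 0.00152, and adjusted p = 0.589 with an estimated correlation. Fibroblast and matrix genes had 0 higher and 11 lower of 20 (0 and 11 adjusted over the list alone). The fibroblast list gave a camera adjusted p of 0.00387, and adjusted p = 0.784 with an estimated correlation. The difference was called for 5665 genes (42.0%), 2996 positive and 2669 negative, and for 4943 without the CD29hiCD24+ array of pool F. The split was 3749 and 2314 after quantile normalisation and 3398 and 2453 after median centring. Negative genes were the larger part with the actin covariate (2100 and 2397) and without pool F (2076 and 2130). Quantile normalisation moved the median of all genes in this difference by 0.12, from 0.04 to 0.16, and every value named here is larger than that. The simulated data gave 35 and 65 of 100 genes at 1 and 2 log2 units.

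Both gate contrasts called 188 genes with the same sign. Of these 101 were higher in CD29hiCD24+ cells, where independent lists would share 64.7 (Fisher's exact test, two-sided p = 1.17e-06), and 87 were lower, where they would share 66 (p = 0.00316). Acta2, Myl9, Adam12 and Elf5 are among the 188. Another 89 genes called in both had opposite signs. Across all 13485 genes, which are not independent replicates, Pearson's r between the normal and the tumour differences was 0.168 and Spearman's rho was 0.000174. The count of 188 became 597 with the replicate block (488 without pool H), 365 with the description-number block, 359 with array weights, 115 at 2-fold and 79 with only the groups compared, and 104, 68 and 100 without tumours A, B and E.

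**Figure D2:**
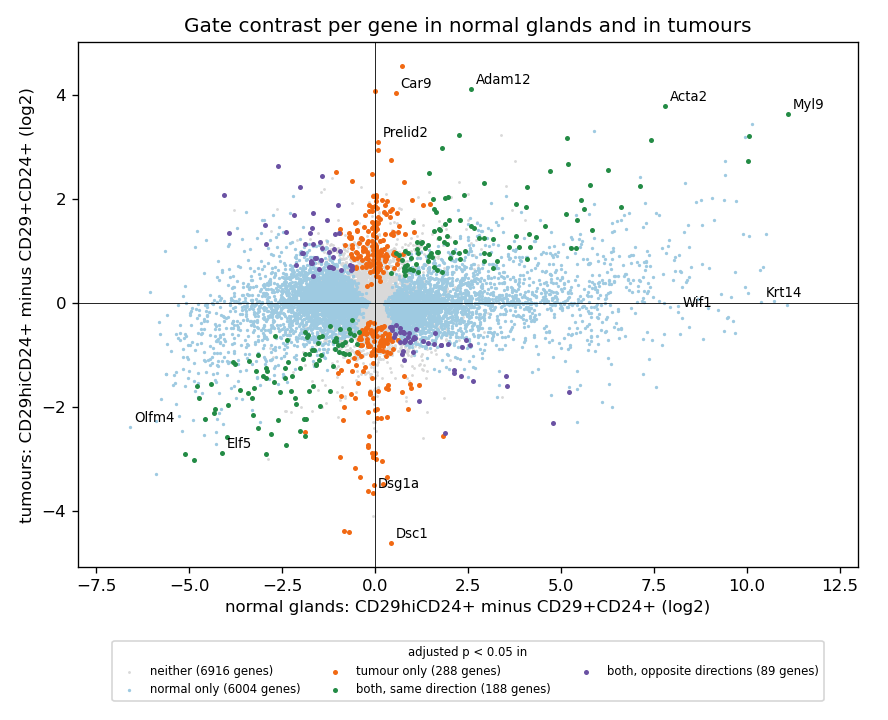
Log2 difference of CD29hiCD24+ minus CD29+CD24+ cells per gene, in normal glands (horizontal axis) and in tumours (vertical axis), for 13485 genes coloured by where the adjusted p was under 0.05. Krt14 lies far to the right near 0 on the vertical axis, Car9 and Dsc1 lie far from 0 on the vertical axis alone, and 188 genes share a direction.

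Against the whole Lin- fraction, normal CD29hiCD24+ cells (n = 3 pools) again had higher basal and lower luminal genes. In the basal list 17 of 20 measured members rose and 0 fell (19 and 0 adjusted over the list alone), with Trp63, the p53-family factor of basal epithelia, at 4.41 ± 0.37 and Oxtr at 4.08 ± 0.80. The basal list had a camera adjusted p of 1.35e-10, and adjusted p = 0.189 with an estimated correlation. In the luminal list 0 of 22 measured members rose and 15 fell (0 and 16 adjusted over the list alone), with Cited1 at -4.81 ± 1.07 and Spdef at -4.27 ± 0.44. The luminal list had a camera adjusted p of 9.92e-05, and adjusted p = 0.490 with an estimated correlation. Highest were Il17b (4.89 ± 0.66), Tenm3 (4.86 ± 0.93), Kcnq5 (4.74 ± 0.59), Nebl (4.73 ± 0.51) and the GDNF receptor Gfra1 (4.72 ± 0.85), and lowest the proteoglycan Lum (-6.71 ± 1.33), Tesc (-6.19 ± 1.22), Rasgrf1 (-5.92 ± 0.93), Dmbt1 (-5.84 ± 1.98) and Olfm4 (-5.70 ± 1.66). Without pool F, Dmbt1 and Olfm4 lost their calls (adjusted p = 0.321 and 0.0950), and Dmbt1 did with only these groups fitted (0.0619) and with the actin covariate (0.0535). Wnt/beta-catenin targets had 15 higher and 1 lower of 19 (17 and 1 adjusted over the list alone), with Lgr5 at 4.06 ± 0.61. The Wnt target list had a camera adjusted p of 1.68e-06, and adjusted p = 0.198 with an estimated correlation. Stem cell genes had 9 higher and 0 lower of 16 (10 and 0 adjusted over the list alone), with Bcl11b at 3.11 ± 0.43. The stem cell list had a camera adjusted p of 4.50e-05, and adjusted p = 0.189 with an estimated correlation. Epithelial junction genes had 0 higher and 14 lower of 20 (0 and 14 adjusted over the list alone). The junction list had a camera adjusted p of 4.50e-05, and adjusted p = 0.189 with an estimated correlation. Fibroblast and matrix genes had 0 higher and 10 lower of 20 (1 and 11 adjusted over the list alone). The fibroblast list had a camera adjusted p of 0.0466, and adjusted p = 0.913 with an estimated correlation. This call was lost with the replicate block (camera adjusted p = 0.178), after quantile normalisation (0.0546) and with the description-number block (0.0768). Endothelial markers had 7 higher and 0 lower of 13 (7 and 0 adjusted over the list alone). The endothelial list had a camera adjusted p of 0.00442, and adjusted p = 0.737 with an estimated correlation. That call was lost with the block (camera adjusted p = 0.0592) and without the CD29hiCD24+ array of pool F (0.0748). In all 5420 genes differed (40.2%), 2294 higher and 3126 lower, and 3491 did without pool F. The simulated data gave 34 and 78 of 100 genes at 1 and 2 log2 units.

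In tumours (n = 5), CD29hiCD24+ cells stood out from the Lin- fraction by low keratinisation and high proliferation genes, and in tumours A, B, C and E by low fibroblast and matrix genes. Among called genes whose groups did not overlap, Dsc1 (-7.55 ± 0.87), Krt1 (-7.26 ± 1.32), the epidermal calmodulin Calm4 (-6.25 ± 0.72), Casp14 (-6.10 ± 0.73) and the protease inhibitor Cst6 (-6.01 ± 0.52) were the lowest. Of the same genes, Car9 (3.95 ± 0.51), Ndufa4l2 (3.61 ± 0.64), Adam12 (3.55 ± 0.54), Prelid2 (3.08 ± 0.24) and H2-Ab1 (2.55 ± 0.68) were the highest. H2-Ab1 lost its call without A, C, D or E (adjusted p up to 0.139). For proliferation 16 of 21 measured members rose and 0 fell (20 and 0 adjusted over the list alone), with the mitotic kinase gene Aurka at 2.30 ± 0.47. The proliferation list had a camera adjusted p of 4.39e-15, and adjusted p = 0.0739 with an estimated correlation. For squamous keratinisation 0 of 17 measured members rose and 9 fell (1 and 11 adjusted over the list alone), with Dsg1a at -5.82 ± 0.47. The keratinisation list had a camera adjusted p of 3.76e-09, and adjusted p = 0.0739 with an estimated correlation. For hypoxia and glycolysis 8 of 18 measured members rose and 1 fell (14 and 1 adjusted over the list alone), with P4ha1 at 1.08 ± 0.22. The hypoxia list had a camera adjusted p of 8.82e-10, and adjusted p = 0.0589 with an estimated correlation. Fibroblast and matrix genes had 0 higher and 14 lower of 20 (0 and 16 adjusted over the list alone), with Col3a1 at -6.02 ± 1.25 and Lum at -5.40 ± 1.03. The fibroblast list had a camera adjusted p of 3.38e-12, and adjusted p = 0.112 with an estimated correlation. In tumour D the list means were 5.70 in the Lin- and 5.52 in the CD29hiCD24+ array, and in the other 4 tumours 7.62 to 10.22 and 5.14 to 6.12. Pericyte markers had 1 higher and 4 lower of 6 (1 and 4 adjusted over the list alone), with Pdgfrb at -3.55 ± 0.77. The pericyte list had a camera adjusted p of 0.00224, and adjusted p = 0.163 with an estimated correlation. Endothelial markers had 0 higher and 1 lower of 13 (0 and 4 adjusted over the list alone). The endothelial list had a camera adjusted p of 0.000331, and adjusted p = 0.444 with an estimated correlation. In tumour E the endothelial means were 3.54 and 3.34, and in the other 4 tumours 3.97 to 6.40 and 3.30 to 3.89. Epithelial junction genes had 0 higher and 9 lower of 20 (0 and 12 adjusted over the list alone), with Tjp3 at -2.08 ± 0.42. The junction list had a camera adjusted p of 6.25e-08, and adjusted p = 0.0694 with an estimated correlation.

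Among other lists in this contrast, basal genes had 1 higher and 0 lower of 20 (4 and 0 adjusted over the list alone), with Dst at 1.29 ± 0.29. The basal list had a camera adjusted p of 0.00129, and adjusted p = 0.472 with an estimated correlation. Luminal genes had 0 higher and 2 lower of 22 (0 and 5 adjusted over the list alone). The luminal list had a camera adjusted p of 0.00405, and adjusted p = 0.501 with an estimated correlation. Wnt ligands had 3 higher and 0 lower of 11 (4 and 0 adjusted over the list alone). The Wnt ligand list had a camera adjusted p of 0.00267, and adjusted p = 0.0694 with an estimated correlation. Interferon response genes had 0 higher and 0 lower of 16 (0 and 0 adjusted over the list alone). The interferon list had a camera adjusted p of 0.0263, and adjusted p = 0.602 with an estimated correlation. This call was lost after quantile normalisation (camera adjusted p = 0.078). Dst lost its call without E (adjusted p = 0.0531), and with only these groups fitted Pdgfrb and Lum lost theirs (adjusted p = 0.0967 and 0.0642). The leukocyte list had 1 higher and 0 lower of 14 (1 and 0 adjusted over the list alone) and was not called (camera adjusted p = 0.417). In all 1128 genes differed (8.36%), 504 higher and 624 lower, and 2531 with the replicate block, all 1128 among them. The split was 792 and 494 after quantile normalisation, 539 and 526 after median centring, 344 and 691 without tumour A and 360 and 324 without tumour C. The count moved to 465 with only these groups fitted, to 1876 with the description-number block, to 667 at 2-fold, and to 745, 684 and 469 without tumours B, C and E. The simulated data gave 59 and 88 of 100 genes at 1 and 2 log2 units.

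Between tumour and normal CD29+CD24+ cells (n = 5 and 3), basal, Wnt pathway and keratinisation genes were higher in tumours. The 5 highest were Wif1 (11.44 ± 0.43), a secreted Wnt inhibitor, Moxd1 (11.17 ± 0.44), Col17a1 (11.14 ± 0.44), Krt5 (11.04 ± 0.46) and Krt17 (10.73 ± 0.53), and the 5 lowest were Fgb (-9.15 ± 1.16), Dmbt1 (-8.74 ± 1.77), Syn2 (-8.18 ± 0.59), the iodide transporter Slc5a5 (-7.88 ± 1.17) and Rbm20 (-7.69 ± 0.82). Basal and myoepithelial genes had 13 higher and 0 lower of 20 (13 and 0 adjusted over the list alone). The basal list had a camera adjusted p of 2.69e-10, and adjusted p = 0.137 with an estimated correlation. Wnt/beta-catenin targets had 15 higher and 0 lower of 19 (15 and 0 adjusted over the list alone), with Apcdd1 at 6.48 ± 0.36 and Nkd2 at 7.35 ± 0.59. The Wnt target list had a camera adjusted p of 8.91e-13, and adjusted p = 0.0488 with an estimated correlation. Stem cell genes had 10 higher and 1 lower of 16 (10 and 2 adjusted over the list alone), with Procr at 7.15 ± 0.61. The stem cell list had a camera adjusted p of 9.77e-07, and adjusted p = 0.0488 with an estimated correlation. Secreted Wnt antagonists had 5 higher and 0 lower of 10 (5 and 0 adjusted over the list alone), with Sostdc1 at 8.29 ± 0.63. The Wnt antagonist list had a camera adjusted p of 0.000127, and adjusted p = 0.0131 with an estimated correlation. Squamous keratinisation genes had 12 higher and 1 lower of 17 (13 and 1 adjusted over the list alone), with Krt16 at 6.98 ± 0.33. The keratinisation list had a camera adjusted p of 7.21e-07, and adjusted p = 0.137 with an estimated correlation. Proliferation genes had 15 higher and 1 lower of 21 (15 and 1 adjusted over the list alone), with Rrm2 at 5.53 ± 0.45. The proliferation list had a camera adjusted p of 5.78e-08, and adjusted p = 0.226 with an estimated correlation. Luminal genes had 3 higher and 16 lower of 22 (3 and 17 adjusted over the list alone), with the oestrogen receptor Esr1 at -7.47 ± 1.26 and Prom1 at -5.69 ± 0.68. The luminal list had a camera adjusted p of 0.00123, and adjusted p = 0.524 with an estimated correlation. Hypoxia and glycolysis genes had 8 higher and 0 lower of 18 (8 and 0 adjusted over the list alone). The hypoxia list had a camera adjusted p of 0.00380, and adjusted p = 0.260 with an estimated correlation. Mesenchymal transition genes had 8 higher and 1 lower of 18 (8 and 1 adjusted over the list alone). The mesenchymal list had a camera adjusted p of 0.000721, and adjusted p = 0.138 with an estimated correlation. Fibroblast and matrix genes had 7 higher and 1 lower of 20 (7 and 1 adjusted over the list alone), with Fbln1 at 6.59 ± 0.52. The fibroblast list had a camera adjusted p of 0.0133, and adjusted p = 0.743 with an estimated correlation. In all 5864 genes differed (43.5%), 2212 higher and 3652 lower, and 5610 did with the description-number block, 4843 of the 5864 among them with the same sign. With that block the tumour level rests on tumour E alone, on genes called with it, so this share is no separate check. The fibroblast list lost its call with the description-number block (camera adjusted p = 0.0724), and the simulated data gave 55 and 92 of 100 genes at 1 and 2 log2 units.

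The Lin- fractions of tumour and normal glands (n = 5 and 3) differed most in keratinisation genes. Krtdap (10.60 ± 0.44), Calm4 (10.11 ± 0.83), Krt6b (10.002 ± 0.496), the skin protease Asprv1 (9.89 ± 0.36) and Serpinb2 (9.37 ± 1.04) were the highest, and Fgb (-9.58 ± 1.16), Dmbt1 (-9.25 ± 1.77), Rbm20 (-8.38 ± 0.82), the tryptophan-degrading enzyme Ido1 (-8.17 ± 1.55) and Slc5a5 (-8.15 ± 1.17) the lowest. Squamous keratinisation genes had 14 higher and 1 lower of 17 (15 and 1 adjusted over the list alone). The keratinisation list had a camera adjusted p of 3.09e-10, and adjusted p = 0.0846 with an estimated correlation. Wnt/beta-catenin targets had 13 higher and 0 lower of 19 (14 and 0 adjusted over the list alone), with Tnfrsf19 at 5.88 ± 0.63. The Wnt target list had a camera adjusted p of 1.13e-09, and adjusted p = 0.117 with an estimated correlation. Secreted Wnt antagonists had 4 higher and 0 lower of 10 (4 and 0 adjusted over the list alone). The Wnt antagonist list had a camera adjusted p of 0.00313, and adjusted p = 0.0792 with an estimated correlation. Stem cell genes had 8 higher and 0 lower of 16 (9 and 0 adjusted over the list alone), with Lgr6 at 2.78 ± 0.47. The stem cell list had a camera adjusted p of 0.00129, and adjusted p = 0.191 with an estimated correlation. Proliferation genes had 15 higher and 2 lower of 21 (16 and 2 adjusted over the list alone), with Top2a at 3.83 ± 0.50. The proliferation list had a camera adjusted p of 1.32e-07, and adjusted p = 0.306 with an estimated correlation. Hypoxia and glycolysis genes had 6 higher and 0 lower of 18 (6 and 0 adjusted over the list alone), with Egln3 at 2.70 ± 0.45. The hypoxia list had a camera adjusted p of 0.00356, and adjusted p = 0.306 with an estimated correlation. Luminal genes had 2 higher and 14 lower of 22 (3 and 16 adjusted over the list alone), with Krt7 at -6.20 ± 1.16. The luminal list had a camera adjusted p of 0.00146, and adjusted p = 0.557 with an estimated correlation. Basal genes went both ways with 9 higher and 7 lower of 20 (9 and 7 adjusted over the list alone), Trp63 at 5.34 ± 0.33 and Cnn1 at -5.38 ± 0.77. The basal list had a camera adjusted p of 0.0490, and adjusted p = 0.700 with an estimated correlation. The call was lost with the description-number block (camera adjusted p = 0.285), after quantile normalisation (0.0887) and without the CD29hiCD24+ array of pool F (0.0543). In all 5470 genes differed (40.6%), 1881 higher and 3589 lower, and 5618 did with the description-number block, 4529 of the 5470 among them with the same sign. Here too the tumour level under the block rests on tumour E alone, on genes called with it, so the share is no separate check. The simulated data gave 48 and 88 of 100 genes at 1 and 2 log2 units.

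**Figure D3:**
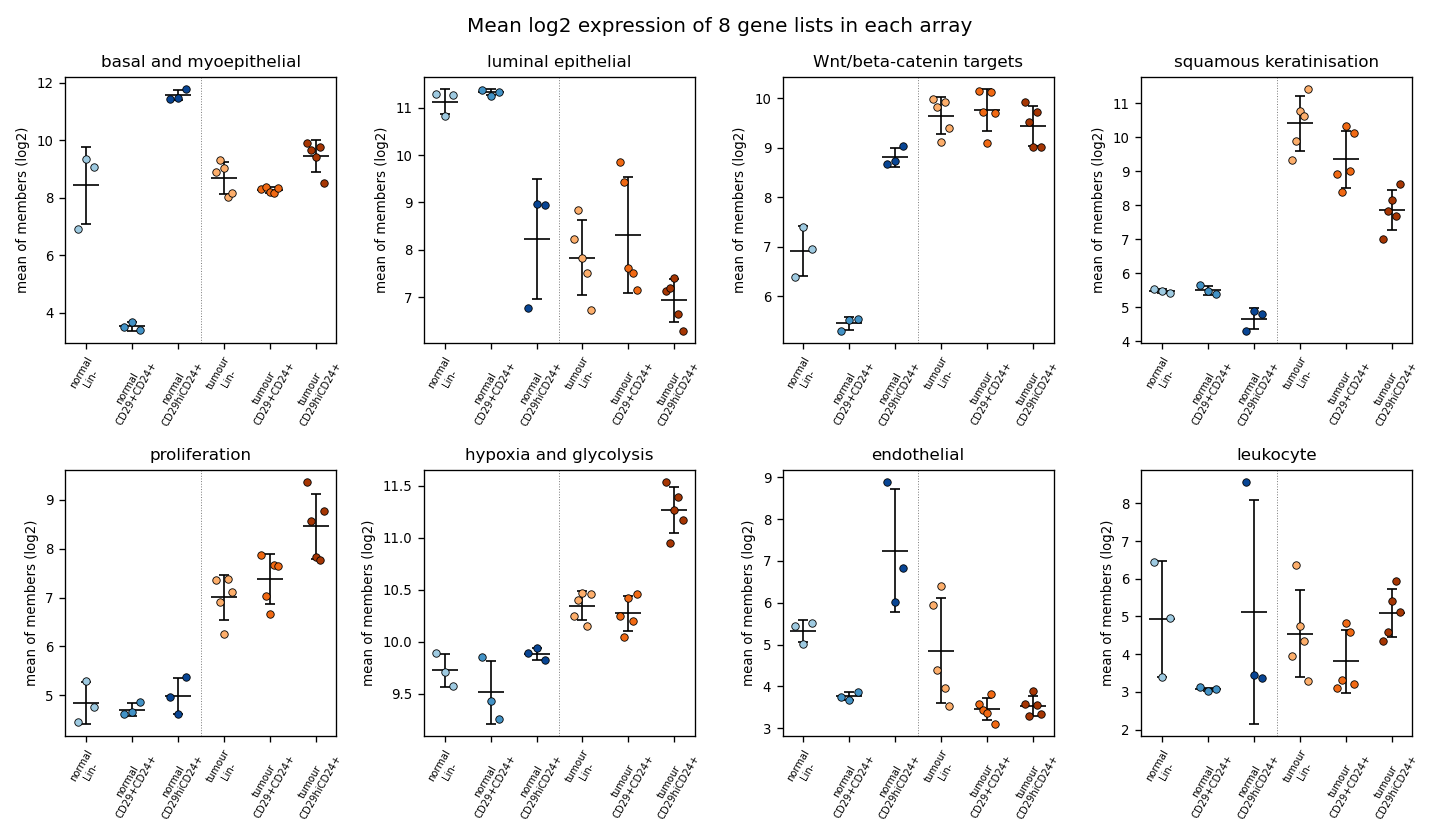
Mean log2 signal of the measured members of 8 gene lists (vertical axis) in each array, by group; points are arrays, bars the mean and standard deviation (n = 3 normal pools, n = 5 tumours). The basal mean is 11.6 in normal CD29hiCD24+ and 3.52 in normal CD29+CD24+ arrays, and 9.44 and 8.26 in the same tumour gates.

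Apc itself was lower in tumours in the CD29+CD24+ (-2.21 ± 0.56, adjusted p = 0.00297) and Lin- populations (-2.47 ± 0.56, adjusted p = 0.00132), and in CD29hiCD24+ cells its difference of -1.41 ± 0.56 did not pass (adjusted p = 0.0538). The Apc difference in CD29hiCD24+ cells was -0.86 and passed without tumour E (adjusted p = 0.00785), whose signal of 8.06 lay under the 10.4 to 10.9 of the others. It passed as well without tumour A (0.0430) or D (0.0498), and with the replicate block (0.0220). With the description-number block the difference was -3.04, but there the tumour level rests on tumour E alone, the tumour with the low signal. A signal level does not show whether a transcript is truncated. Itgb1 (CD29) differed by 0.90 ± 0.38 between CD29hiCD24+ and CD29+CD24+ cells in normal glands (adjusted p = 0.0588) and by 0.60 ± 0.29 in tumours (adjusted p = 0.268), neither past the threshold. With the replicate block the normal difference of Itgb1 passed (adjusted p = 0.0146), as it did without the CD29hiCD24+ array of pool F (1.16, adjusted p = 0.0296) and with the actin covariate (1.88, adjusted p = 2.27e-05), and the tumour one passed with array weights (adjusted p = 0.0438). Itgb1 was higher in normal CD29hiCD24+ than in Lin- cells (1.18 ± 0.38, adjusted p = 0.0170), a call lost without pool G (adjusted p = 0.225) and with only these groups fitted (0.111). Cd24a (CD24) was lower in normal CD29hiCD24+ than in CD29+CD24+ cells (-1.07 ± 0.19) and lower in tumours than in normal glands in CD29hiCD24+ (-0.81 ± 0.17), CD29+CD24+ (-1.47 ± 0.17) and Lin- cells (-1.45 ± 0.17). Between the tumour gates it differed by -0.41 ± 0.15 (adjusted p = 0.120), and past the threshold without tumour D (-0.52, adjusted p = 0.0451).

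**Figure D4:**
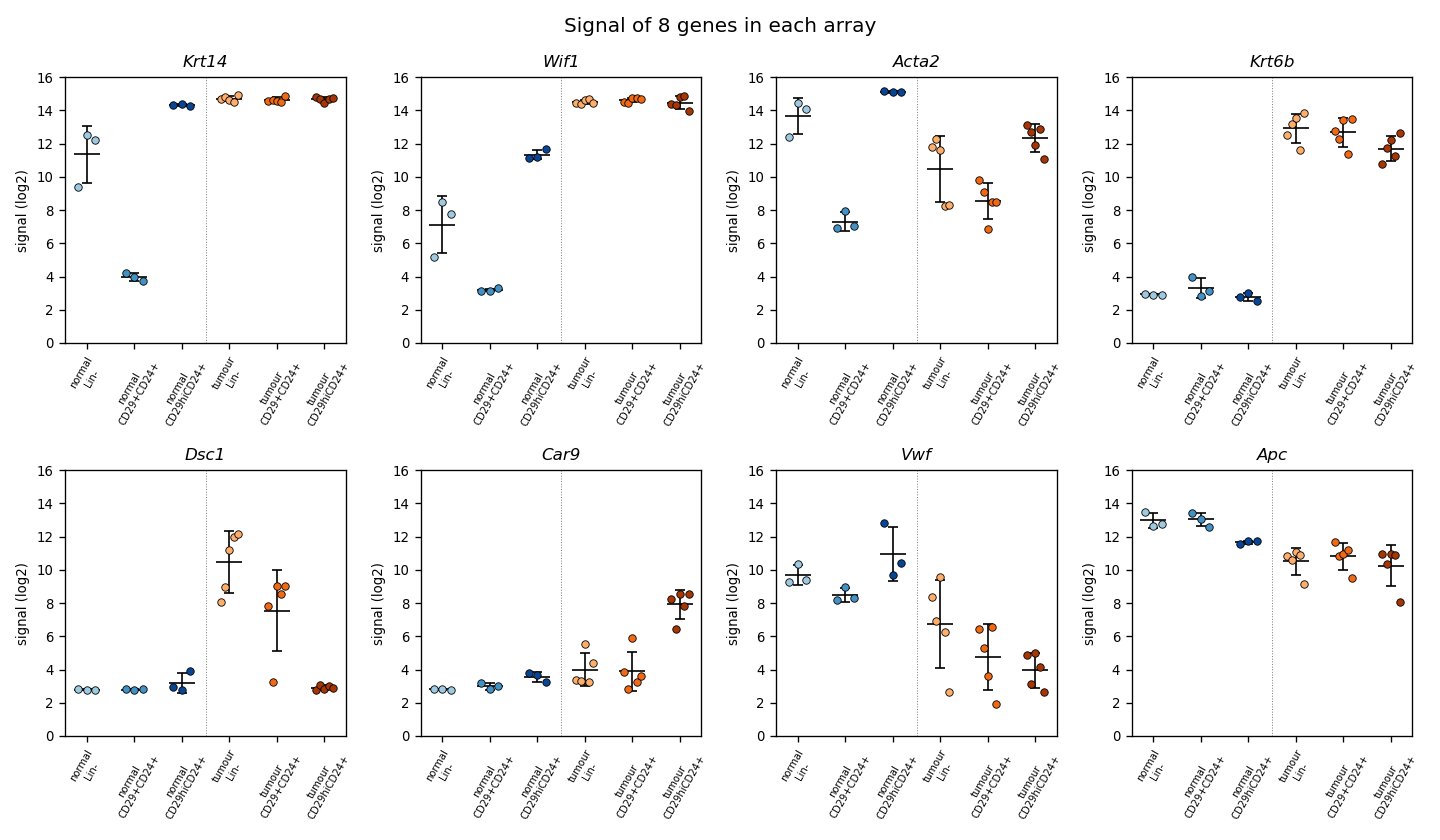
Log2 signal of 8 genes (vertical axes) in each array, by group; points are arrays, bars the mean and standard deviation (n = 3 normal pools, n = 5 tumours). Krt14 and Wif1 are high in all tumour populations, Car9 is highest in tumour CD29hiCD24+ arrays, and Apc is low in tumour E in 2 populations (8.06 and 9.13).

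Of the 184 tests of a list in a contrast, camera called 71 (47 higher, 24 lower), and the median, the mean and the test of each called list had the same sign. With an estimated correlation 7 calls held, namely basal, stem cell and Wnt antagonist genes between the normal gates, hypoxia genes between the tumour gates, and stem cell, Wnt target and Wnt antagonist genes between tumour and normal CD29+CD24+ cells. Fry, which tests whether a list's genes move on balance to 1 side and does not compare them with other genes, called 83 lists, 62 of the 71 among them.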

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

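The 3 weighings below rest on tests chosen only after the results were seen. The splits of the samples, the search for outlying arrays and the direct test of the gate contrasts were planned.

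Gate contrasts differed between tumour and normal glands for 5665 genes, and among lists for basal and myoepithelial (median log2 -6.90), mammary stem cell associated (-3.11), Wnt/beta-catenin target (-2.62), secreted Wnt antagonist (-2.53), mesenchymal transition (-2.45), fibroblast and matrix (-3.64), endothelial (-3.30) and epithelial junction genes (1.45). Fewer genes part the gates in tumours (565) than in normal glands (6281). With the replicate block, which keeps the pairs, the counts were 2080 and 7282, a smaller gap. A larger spread among tumours argues for small tumour differences being missed, yet over the 6281 genes called in normal glands the ratio of the tumour to the normal difference had a median of -0.01 and an upper quartile of 0.141, so the differences themselves were smaller. Mixing of 1 tumour gate into the other would shrink the tumour's own differences without turning them. There were 89 tumour calls opposite to a normal call, where the threshold lets 28.25 of all tumour calls through by error. These 89 decide nothing on mixing, since tumour differences need not have had the normal sign before it. Which cells each gate holds in a tumour stays open, and tumour and normal differ in genotype and tissue by design, so a biological difference between them may account for the pattern and was not tested apart from them.

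Endothelial markers were lower in tumour than in normal CD29hiCD24+ arrays. RNA of other cells in the array of pool F alone is argued against by 10 of 13 markers that were still lower without that array, the exceptions being Egfl7, Eng and Robo4. Whether endothelial cells fell in the normal CD29hi gate stays open. In each normal CD29hiCD24+ array 11 of the 13 markers were higher than in every normal CD29+CD24+ array (8 by over 1 log2 unit), the exceptions being Egfl7 and Eng, but this restates the gate contrast, and the fibroblast, pericyte and adipocyte means lay apart in the same way. It does not tell either whether tumour vessels are fewer or sort elsewhere.

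Hypoxia and glycolysis genes were higher in tumour CD29hiCD24+ than in CD29+CD24+ arrays. Shortening of RNA as the whole cause is argued against by actin 3' minus 5' signals that were alike in the 2 gates (2.03 ± 0.30 and 2.06 ± 0.36, SD, n = 5 each). With this signal as covariate 9 of 9 called members stayed called (median log2 1.25 before and 1.22 after). A covariate that hardly differs between the gates could not have removed the difference, so this adds little. With the leukocyte mean as covariate 7 of 9 stayed called, and the median was 1.30 after (median standard error 0.29 before and 0.31 after). The list mean was higher in 5 of 5 tumours, but both gates of a tumour lie in the same range of description numbers, so this decides nothing about the description-number ranges. The slope on the leukocyte mean was fitted over all 24 arrays. That mean had an SD of 2.98 in normal CD29hiCD24+ arrays, against 0.64 and 0.83 in tumour CD29hiCD24+ and CD29+CD24+ arrays. The slope thus rests largely on normal arrays, and leukocyte RNA in the tumour gates stays open. Position of the cells in the tumour, time between excision and sorting, and cell types other than leukocytes stay open too and were not tested.

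Other splits of the samples into groups of the same sizes tested chance. Of 56 splits of the 8 arrays, 1 (the real split) gave as many genes in each tumour against normal contrast. This argues against chance, at the smallest share that 56 splits allow. The counts were 5199 against at most 1647 in another split for CD29hiCD24+, 5864 against 2801 for CD29+CD24+, and 5470 against 1816 for Lin- cells. Those highest splits put 2 tumours of the same number range with the 3 pools (C and D in the first, A and B in the others). For the difference of the gate contrasts, 56 splits of the tumours and pools gave 5665 against at most 4. Every other split there puts tumour and normal arrays into 1 group, so their large differences enter the spread. This holds the count down in advance, so these splits do not test the difference of the gate contrasts by itself. For contrasts within tumours, 1 of 100 splits drawn (the real one) gave as many genes, with 565 against at most 49 for the gates and 1128 against 294 for CD29hiCD24+ against Lin- cells. These splits ignore that the arrays come from the same tumours, so they argue against chance only for arrays taken as independent. Joint regroupings of normal and tumour arrays gave at most 0 genes that changed alike, against 188. Regrouping breaks both gate contrasts, which fixes a count near 0 in advance, so this does not test the sharing. Only 10 splits exist for 3 arrays against 3, too few for a share under 0.05, and the real ones gave 6281 against at most 3 and 5420 against at most 25. When the gates are swapped within tumours or pools and the pairs kept, with the replicate block, the real splits gave 2080 against at most 3 and 2531 against at most 73 in 16 splits, and 7282 against 1 and 6573 against 17 in 4 splits. Both 16 and 4 splits are too few for a share under 0.05.

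Single arrays stood apart from the others of their group in 6 of 81 tests, where chance gives 4.05. Tumour A had a milk and secretory mean of 9.13 in CD29hiCD24+ cells (others 4.91 to 5.83). Tumour E had a mesenchymal transition mean of 6.85 in CD29hiCD24+ cells (others 7.14 to 7.21), and Apc signals of 8.06 in CD29hiCD24+ cells (others 10.4 to 10.9) and 9.13 in Lin- cells (others 10.6 to 11.1). Tumour C had a skeletal muscle mean of 3.78 in CD29+CD24+ cells (others 2.99 to 3.16) and an adipocyte mean of 5.13 in Lin- cells (others 4.43 to 4.63). Among 5637 kept probe sets with no single gene name, which no other result uses, 854 (15.2%) differed between tumour and normal CD29hiCD24+ cells, 281 higher and 573 lower.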

How the results depend on the processing

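Of the alternatives, 3 were chosen only after the results were seen (without the CD29hiCD24+ array of pool F, tumour E alone, and the leukocyte covariate), and the others were planned. No count of genes moved by more than 1.5 times except those that follow, and where no reason is given the cause was not tested. A 2-fold threshold gave 3418 genes for tumour against normal CD29hiCD24+ cells, 304 and 667 for tumour CD29hiCD24+ against CD29+CD24+ and against Lin- cells, and 115 genes changed alike in both gate contrasts, since it keeps a part of the called genes by construction. The replicate block gave 2080, 2531 and 597 for the last 3 of these (488 for the shared genes without pool H), and it changed no other count by more than 1.5 times and no call of a list but those given with it. The description-number block gave 1263, 1876 and 365, a fit of only the groups compared, which has fewer arrays behind its spread, gave 149, 465 and 79, and array weights gave 1028 for the tumour gates and 359 shared genes. Leaving out each tumour or pool gave 4231 to 5319 genes for tumour against normal CD29hiCD24+, 4854 to 6016 for CD29+CD24+ and 4464 to 5458 for Lin- cells, 4665 to 6400 and 3491 to 5569 for normal CD29hiCD24+ against CD29+CD24+ and Lin- cells, 207 to 565 and 469 to 1042 for the same tumour contrasts, 4206 to 5637 for the difference of gate contrasts, and 68 to 170 shared genes. Without pool F the normal CD29hiCD24+ against Lin- count was 3491. Without tumours A, B, C and E and pool H the tumour gates gave 297, 207, 340, 245 and 371 genes. For tumour CD29hiCD24+ against Lin- cells the counts without B, C and E were 745, 684 and 469, and for the shared genes those without A, B and E were 104, 68 and 100. Tumour E alone was set against the pools on genes called with it among the arrays, which fixes a high share in advance, so that share is not given. Without the CD29hiCD24+ array of pool F, 4414 genes differed between tumour and normal CD29hiCD24+ cells, 4194 of them (80.7% of 5199) with the same sign as before. With the leukocyte mean as covariate 419 genes differed between the tumour gates, 371 of the 565 among them. Called lists numbered 71 with camera at the preset correlation, 7 with an estimated one, 83 with fry and 68 to 77 under the other alternatives. Values of named genes were recomputed 15909 times over contrasts and alternatives. Of these 15174 kept their direction and side of the threshold, 655 lost a call, 79 gained one and 1 turned, Mbp between the normal gates with the mean of its probe sets (0.15, adjusted p = 0.80, against -1.02 before), where 2 of its 3 other probe sets go the other way. Values of lists were recomputed 1288 times, 1158 keeping their call, 90 losing and 40 gaining it, with 0 turned. With signals in the low band, at or under 2.83, differences are compressed, so the largest log2 values named are limited by background.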

Other observations

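Notch pathway genes were called higher in tumour CD29+CD24+ cells, with 6 higher and 1 lower of 14 (6 and 1 adjusted over the list alone), Jag2 at 6.26 ± 0.43 and Notch1 at 2.15 ± 0.34. The Notch list had a camera adjusted p of 0.0132, and adjusted p = 0.173 with an estimated correlation. In tumour Lin- cells the same genes had 5 higher and 0 lower of 14 (5 and 0 adjusted over the list alone), with Nrarp at 2.48 ± 0.49. The Notch list had a camera adjusted p of 0.00825, and adjusted p = 0.191 with an estimated correlation. This call was lost with the description-number block (camera adjusted p = 0.0558). Immediate early genes, which tissue dissociation also induces, were called higher in tumours in CD29hiCD24+ cells, with 7 higher and 0 lower of 20 (8 and 1 adjusted over the list alone), Fosb at 1.96 ± 0.37 and Atf3 at 1.39 ± 0.28 (camera adjusted p = 0.0468, adjusted p = 0.785 with an estimated correlation), a call lost with the replicate block (camera adjusted p = 0.056) and with the description-number block (0.425). They were called higher in tumour Lin- cells too, with 6 higher and 0 lower of 20 (6 and 0 adjusted over the list alone), Klf4 at 1.07 ± 0.09 and Hspa1a at 1.08 ± 0.17. The immediate early list had a camera adjusted p of 0.00825, and adjusted p = 0.663 with an estimated correlation. Here too the call was lost with the description-number block (camera adjusted p = 0.255). In the normal gland the Wnt ligands parted by gate, with 4 higher and 4 lower of 11 (4 and 4 adjusted over the list alone), Wnt10a higher (5.54 ± 0.51) and Wnt4 (-3.95 ± 0.56) and Wnt5a (-2.87 ± 0.44) lower in CD29hiCD24+ cells, and the list was not called (camera adjusted p = 0.828).

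The next 5 lists were called by camera in no contrast in the main setting, though fry called all of them but skeletal muscle in at least 1. With no low-value filter, skeletal muscle genes were called higher in tumour CD29hiCD24+ than in Lin- cells (camera adjusted p = 0.0447, against 0.0762 with the filter). For tumour against normal CD29hiCD24+ cells, the milk and secretory list had 1 higher and 4 lower of 14 (1 and 4 adjusted over the list alone), with Xdh at 1.58 ± 0.38 (camera adjusted p = 0.711). The adipocyte list had 0 higher and 3 lower of 7 (0 and 3 adjusted over the list alone), with Cd36 at -5.94 ± 0.62 and Fabp4 at -6.03 ± 1.23 (camera adjusted p = 0.315). Skeletal muscle genes had 2 higher and 0 lower of 6 (2 and 0 adjusted over the list alone), with Myh1 at 2.14 ± 0.52 (camera adjusted p = 0.254). Schwann and glial genes had 1 higher and 2 lower of 7 (1 and 2 adjusted over the list alone), with Pmp22 at -2.64 ± 0.56 and Erbb3 at 2.04 ± 0.27 (camera adjusted p = 0.994). Hair follicle genes had 3 higher and 1 lower of 8 (3 and 1 adjusted over the list alone), with Krt73 at 3.41 ± 0.54 and Msx2 at 2.26 ± 0.51 (camera adjusted p = 0.315). The leukocyte list had 1 higher and 1 lower of 14 (0 and 0 adjusted over the list alone) in that contrast (camera adjusted p = 0.958). Without the CD29hiCD24+ array of pool F, an alternative chosen after the result was seen, it was called higher in tumours (camera adjusted p = 0.0268), as were interferon response genes (camera adjusted p = 0.011, and 0.133 with that array).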
